A study of Mus musculus with 6 samples.

How the data were processed

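Gene expression was measured by RNA sequencing in splenic follicular (Fo) B cells of mice aged 8 weeks. Per the labels, the cells were sorted as B220-positive and CD93-negative cells with low CD21 and high CD23. B220 is a surface form of CD45 on B cells, CD93 marks immature B cells, CD21 is the product of Cr2 and CD23 that of Fcer2a. Of the 6 libraries, 3 came from C57BL/6 (B6) control mice, called WT here, and 3 from mice homozygous for the G9gl knock-in. Each library was assigned to its group by the genotype and title in the labels. No label states that the 3 libraries of a group came from separate animals, so all p-values measure only the spread between these samples, which may be technical.

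Per the labels' protocols, total RNA was extracted with Trizol, full-length cDNA was made with a SMART-Seq HT kit and libraries were prepared with a Nextera kit. This kind of library keeps no strand information, so overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 were used with the mouse build mm10. The values deposited by the authors are FPKM per gene symbol, that is fragments per kilobase of transcript, scaled to the number of mapped fragments. That unit was read from the tools and from the values, which are not whole numbers and whose totals differ between libraries. The annotation, any filter and any scaling between libraries are not given in the sources used here.

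FPKM divides by transcript length and by all mapped fragments, so a change in a few abundant transcripts shifts the values of all other genes. Immunoglobulin genes, whose transcripts are abundant in B cells, were not analysed here. For that reason the planned comparison of endogenous immunoglobulin variable genes, which would have checked the genotype labels, was not made, nor was the planned rescaling without these genes. FPKM totals and the rescaling to TPM therefore cover the other genes alone, so that rescaled values are shares of these genes and not of all transcripts. The panel genes Ighm and Ighd and the 2 immunoglobulin lists gave no value for the same reason.

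The tables held 24346 gene symbols, each with 1 value per library. The FPKM values summed to 603054 to 611557 in the WT libraries and to 657759 to 671533 in the G9gl libraries. No counts were used, and depth was estimated in genes with a single annotated transcript of at least 1500 bases. The estimate rests on the FPKM value that 1 fragment gives, sought only within a preset range. This gave 9270000 to 10910000 fragments per library, so that an FPKM of 1 in a transcript of 2 kb rests on about 18.6 to 21.8 fragments. At most 2 genes had identical values above 0 in any pair of libraries, so no library was a copy of another.

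Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 10122. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), with genotype as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene is called higher or lower in G9gl at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Errors are SD over 3 libraries for FPKM and standard errors from the limma fit for log2 fold changes.

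Before the data were examined, 34 gene lists were written from textbook knowledge, covering signalling, B cell states and subsets, metabolism, stress and other cell types. The 27 lists with at least 5 tested members were tested with limma's camera, two-sided, with its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. camera with an estimated correlation and limma's fry were run beside it. For each list the number of members called over all genes and adjusted over the list alone is given.

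The rule for naming genes was also fixed before the data were examined. It took a panel of B cell genes, the 12 genes with the largest and the 12 with the lowest log2 fold change among called genes whose libraries do not overlap between groups, and up to 4 members with the smallest p from each list. Some genes that this rule took are not reported here. Predicted genes, Riken clones and small RNA genes were not named among the 24. Members named to complete a count of 5 or fewer, and neighbours of genes along a chromosome, were chosen after their values were seen.

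Gene positions, GC content and transcript lengths came from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes. They were matched by symbol, and 96.2% of tested genes had a GC content and length. Coordinates are 1-based.

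The alternatives planned before the data were examined were other pseudocounts, other filters on low values, quantile normalization, median-ratio scaling, library weights, a robust eBayes fit, a replicate block, and leaving out each library in turn. A rescaling to TPM and the removal of a trend on GC content and transcript length, fitted per library with mgcv 1.9.3, were added after the data were seen. The gene and list tests were tested on simulated data with the spread of the 10122 tested genes in the comparison of G9gl with WT. Of the genes changed 1.5-fold the test recovered 82.1%, of those changed 2-fold 98.5% and of those changed 4-fold 100%. It called 8 of 9882 unchanged genes. The shifted list was found and 0 of 20 unshifted lists were called. That count may not hold for lists whose genes move together. In the data the estimated correlation was 0.57 for ribosomal protein genes and 0.60 for interferon genes.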

Results

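The transcriptomes of splenic Fo B cells were compared between WT mice and mice homozygous for the G9gl heavy and light chains, with 3 libraries per genotype. Fo B cells are the recirculating mature B cells of the splenic follicles. G9gl is the germline form of a DNA-binding antibody from a person with lupus, and its carriers were compared with WT to learn about the anergic state of their B cells. Anergy is a state in which a self-reactive B cell persists but responds weakly to its antigen. Each library was estimated to hold 9270000 to 10910000 fragments, and 13467 to 14908 genes were above 0 FPKM in the WT libraries against 14823 to 16187 in the G9gl libraries.

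Ctse, which encodes the aspartic protease cathepsin E, rose most in G9gl among the named genes, from 6.71 ± 1.19 to 209.7 ± 55.0 FPKM (SD, n = 3 per group, as for all values below). Apoe, which encodes a lipid transport protein, was among the most abundant genes that rose, from 223 ± 22.6 to 1157 ± 141 FPKM, and Serpina3g, a serine protease inhibitor gene, rose from 40.4 ± 4.33 to 299 ± 35.9 FPKM. The largest decreases included S100a6, a calcium-binding protein gene, from 13.1 ± 1.90 to 1.54 ± 0.567 FPKM, Akt1, a kinase gene downstream of PI3 kinase, from 58.3 ± 1.64 to 16.3 ± 6.14 FPKM, and Fgd2, a guanine nucleotide exchange factor gene, from 123 ± 7.33 to 35.2 ± 3.30 FPKM. In all, 1191 genes were called higher and 1174 lower in G9gl among 10122 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 149 were higher and 108 lower by at least 2-fold.

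Ctse (chromosome 1, 131638306 to 131675505, mm10) had a log2 fold change of 4.75 ± 0.19 (SE) and a limma adjusted p of 7.7e-07, a 26.8-fold rise. Il9r (chromosome 11, 32187541 to 32200279), the gene of the interleukin-9 receptor, rose 12.9-fold, from 7.09 ± 0.987 to 103 ± 9.71 FPKM (adjusted p 1.0e-07). The neighbouring serpin genes Serpina3f (chromosome 12, 104214544 to 104221129) and Serpina3g (chromosome 12, 104236245 to 104241939) rose 10.7-fold and 7.24-fold. They are near copies of one another, so fragments could be split between them. Lilrb4a (chromosome 10, 51490956 to 51496611), which encodes an inhibitory receptor, rose 9.04-fold, from 0.891 ± 0.133 to 16.1 ± 0.411 FPKM. Fcer1g (chromosome 1, 171229572 to 171234365), the gene of the Fc receptor gamma chain, rose 7.56-fold, from 3.21 ± 1.10 to 30.8 ± 7.33 FPKM. Tbx21 (chromosome 11, 97098071 to 97115331), which encodes the transcription factor T-bet, rose 5.51-fold, from 2.46 ± 1.06 to 17.5 ± 3.23 FPKM. The chemokine gene Ccl4 rose 7.62-fold, Rhbdf1, which encodes an inactive rhomboid protease, 8.44-fold, Rgl1, a Ral exchange factor gene, 6.06-fold, the interferon-induced Ifitm3 5.17-fold and Apoe (chromosome 7, 19696109 to 19699188) 5.15-fold, with adjusted p from 7.6e-08 for Rgl1 to 3.4e-04 for Ifitm3.

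Among the genes that fell, Shisa8 (chromosome 15, 82206168 to 82212815) dropped from 9.9999 ± 0.474 to 0.921 ± 0.126 FPKM, a 5.73-fold decrease with an adjusted p of 1.7e-06. Rnpep (chromosome 1, 135262712 to 135284084), which encodes an aminopeptidase, fell 5.60-fold and S100a6 (chromosome 3, 90612882 to 90624181) 5.59-fold. Gna12 (chromosome 5, 140758408 to 140830431), a G protein alpha subunit gene, fell 5.51-fold, from 19.3 ± 1.89 to 2.95 ± 1.78 FPKM. Spns2, a sphingosine-1-phosphate transporter gene, fell 4.32-fold, and Ybx3, a gene of a nucleic acid-binding protein, 4.12-fold. Hepacam2 fell 4.12-fold, the intramembrane protease gene Sppl3 3.70-fold and Nfam1, which encodes a receptor with an immunoreceptor tyrosine-based activation motif, 3.66-fold. Akt1 (chromosome 12, 112653821 to 112674884) fell 3.59-fold, the small GTPase gene Rab21 3.51-fold and Fgd2 (chromosome 17, 29360914 to 29379661) 3.44-fold. The largest adjusted p among these 12 genes was 3.3e-04, for Akt1. Akt1, Serpina3f and Serpina3g lie within 10 Mb of the Igh locus, which spans 113254830 to 116010093 on chromosome 12.

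**Figure D1:**
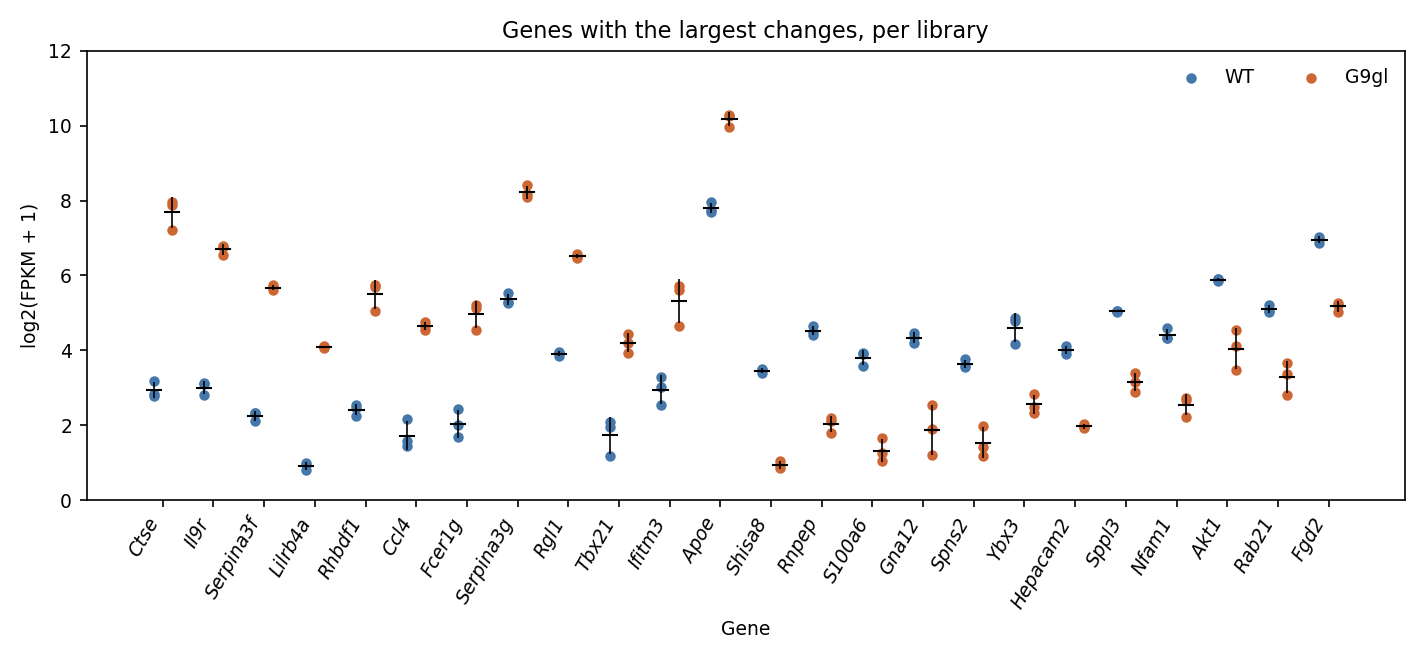
The 12 genes with the largest and the 12 with the lowest log2 fold change by the naming rule, with log2(FPKM + 1) on the vertical axis. Each point is 1 library, and bars give the mean and SD of 3 libraries in WT (blue) and G9gl (orange). For each gene the 3 libraries of one genotype lie above the 3 of the other.

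The panel of B cell receptor (BCR) response and maturation genes moved in both directions. Egr2, an early transcription factor gene that BCR signals induce, rose 4.03-fold, from 7.10 ± 0.542 to 31.6 ± 0.738 FPKM (log2 fold change 2.01 ± 0.081 SE, limma adjusted p 8.7e-07). Cd83, an activation marker gene, rose 2.09-fold, from 324 ± 14.7 to 684 ± 112 FPKM (adjusted p 9.4e-05). Cr2, which encodes CD21, fell 2.13-fold, from 131 ± 7.20 to 61.2 ± 2.42 FPKM (adjusted p 5.2e-06). Cd86, a costimulatory ligand gene, fell 1.43-fold (adjusted p 0.0063) and Fcer2a, which encodes CD23, 1.19-fold (adjusted p 0.010). CD21 and CD23 were part of the sort gate.

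Myc rose 1.45-fold, from 48.6 ± 3.48 to 72.7 ± 22.3 FPKM (adjusted p 0.047), with 98.4 FPKM in G9gl replicate 1 against 61.5 and 58.2 in the other G9gl libraries. The call for Myc was lost in 9 of the alternative settings. Nr4a1, the gene of the orphan receptor Nur77 that reports BCR signalling, did not pass the test, with 31.9 ± 6.83 FPKM in WT and 42.7 ± 33.9 FPKM in G9gl (adjusted p 0.80). Its value was 81.8 FPKM in G9gl replicate 1 and 21.2 and 25.1 in replicates 2 and 3, and without replicate 1 its log2 fold change was -0.43 with an adjusted p of 0.091. Cd69, an early activation marker gene, had 103 ± 30.2 FPKM in WT and 178 ± 74.0 FPKM in G9gl (adjusted p 0.074). Egr3 (adjusted p 0.90), Cd5 (adjusted p 0.13), Nfatc1 (adjusted p 0.11), Cd93 (adjusted p 0.61) and Ptprc (adjusted p 0.15) did not pass. With values rescaled to TPM, Nfatc1 and Ptprc passed as lower (adjusted p 0.013 and 0.010).

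**Figure D2:**
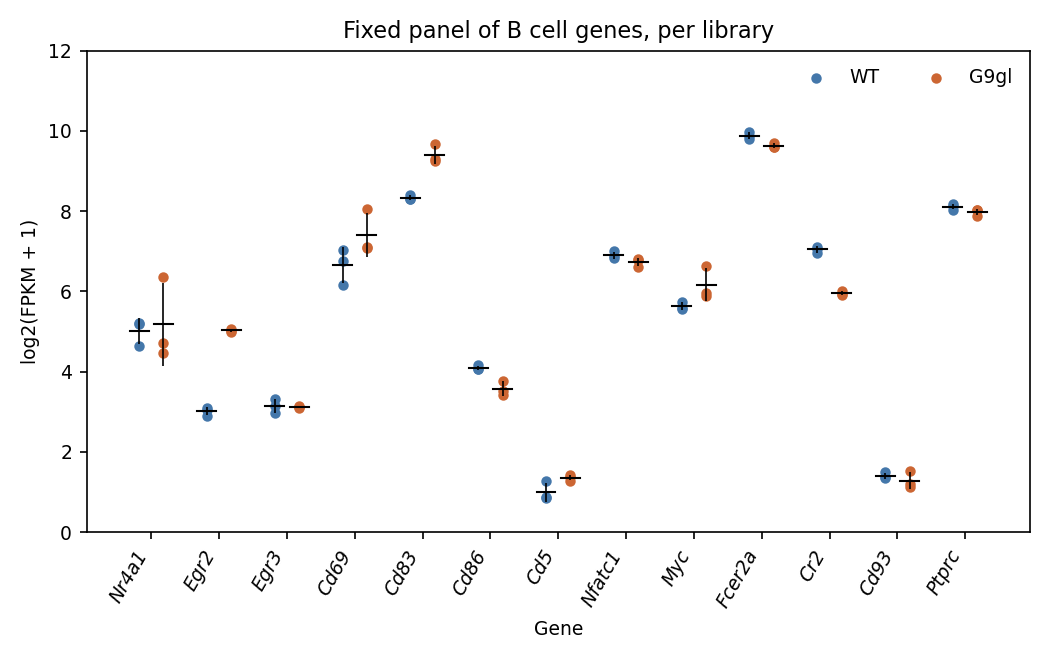
The 13 panel genes with values, with log2(FPKM + 1) on the vertical axis. Points are libraries and bars the mean and SD of 3 libraries in WT (blue) and G9gl (orange). Nr4a1, Cd69 and Myc have 1 G9gl library, replicate 1, above the other 2.

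Of the 32 tested genes on the list of early genes induced by BCR signals, 14 rose, 6 fell and 12 did not pass. Adjusted over the list alone, 16 were higher and 7 lower. Egr2 rose 4.03-fold, Bcl2a1b, an anti-apoptotic gene of a family of near copies, 1.92-fold, and the chemokine genes Ccl3 and Ccl4 4.203-fold and 7.62-fold. The list was shifted up (median log2 fold change 0.35, camera adjusted p 0.011), with an adjusted p = 0.35 with an estimated correlation. Without G9gl replicate 1 the camera adjusted p was 0.077, and without a filter on low values 0.060. The median was 0.23 with values rescaled to TPM. Beside it, 8 of 20 tested genes of cell dissociation and heat-shock stress rose and 2, Jund and Btg2, fell, among them Hsp90aa1, a chaperone gene, from 84.5 ± 10.8 to 125 ± 2.58 FPKM, and Btg2, an antiproliferative gene, from 217 ± 6.96 to 123 ± 2.60 FPKM. Adjusted over the list alone 14 were higher and 2 lower. After quantile normalization or a rescaling to TPM 5 were higher, with a list median of 0.23 and 0.22, and 1 was lower without WT replicate 1 or 2 or without G9gl replicate 2 or 3. The stress list was shifted up (median 0.35, camera adjusted p 0.0060, adjusted p = 0.35 with an estimated correlation).

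Of 25 tested genes on the anergy list, 4 rose, 10 fell and 11 did not pass. Adjusted over the list alone, 4 were higher and 11 lower. Those that rose were Egr2, Ndrg1, Cd72 and the inhibitory receptor gene Lag3. Ndrg1, which has been tied to lymphocyte tolerance, rose 4.71-fold, from 2.98 ± 0.176 to 17.8 ± 2.21 FPKM, and Cd72, an inhibitory coreceptor gene, 2.05-fold, from 461 ± 20.2 to 944 ± 30.5 FPKM. Cblb, which encodes a ubiquitin ligase that dampens antigen receptor signals, fell 1.74-fold, from 22.7 ± 0.801 to 12.6 ± 0.833 FPKM. The list as a whole was not shifted (camera adjusted p 0.79, adjusted p = 0.79 with an estimated correlation), and its median log2 fold change of -0.14 and its mean of 0.14 differed in sign. That is a test for a shift in a single direction. The fry adjusted p, which does not compare the list with other genes, was 0.0057. Of all tested genes 23.4% were called, against 4 higher and 10 lower of the 25 on this list. The number lower depended on single libraries, with 3 lower without WT replicate 2, 5 without G9gl replicate 2 or 3 and 6 without WT replicate 1 or 3, against 4 higher each time. It was 5 with a trend on GC content and transcript length removed and 6 without a filter on low values, and the median was then -0.078 and 0.00069, against -0.094 without WT replicate 3 and -0.27 with values rescaled to TPM.

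Inhibitory receptors and phosphatases of the BCR also went both ways. Of 24 tested, 5 rose (Cd22, Fcgr2b, Cd72, Lilrb4a and Btla), 6 fell and 13 did not pass, the same counts as adjusted over the list alone, while 3 rose with values rescaled to TPM. Pirb, an inhibitory receptor gene, fell 1.67-fold, from 35.8 ± 0.610 to 21.1 ± 1.54 FPKM, and Siglecg, a sialic acid-binding inhibitory receptor gene, 1.33-fold, from 282 ± 13.9 to 212 ± 5.34 FPKM. The camera adjusted p was 0.55, and the adjusted p = 0.73 with an estimated correlation. The proximal BCR signalling list was shifted down, with 4 of 30 tested genes higher, 10 lower and 16 not passing (median -0.13, camera adjusted p 0.027, adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone, 4 were higher and 13 lower, with values rescaled to TPM 2 were higher and 20 lower (median -0.26), and after quantile normalization 3 and 16 (median -0.20). Without WT replicate 2 or 3, or G9gl replicate 2 or 3, 2 were higher. Prkcb, the gene of protein kinase C beta, fell 1.53-fold, from 141 ± 4.87 to 92.0 ± 6.05 FPKM. The 4 that rose were Blk, a Src-family kinase gene (1.32-fold), Rasgrp3, a Ras activator gene (1.43-fold), the adaptor gene Blnk and Bcl10. The camera call for this list was lost in 4 alternative settings, with adjusted p up to 0.061.

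Type I interferon response genes rose together in G9gl, with 22 of 32 tested higher, 0 lower and 10 not passing. Adjusted over the list alone 27 were higher. Zbp1, a nucleic acid sensor gene, rose 2.32-fold, from 35.7 ± 0.432 to 84.3 ± 6.98 FPKM. Isg20, an exonuclease gene, rose 1.65-fold and Oas1a, an oligoadenylate synthetase gene, 2.17-fold. The median log2 fold change was 0.68 (camera adjusted p 2.6e-11), with an adjusted p = 0.39 with an estimated correlation. Without G9gl replicate 1, 28 members were called higher, and without any 1 of the other libraries 18. Macrophage markers, given below, rose in the same libraries.

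Antigen presentation genes were higher as well, with 15 of 23 tested called higher, 1 (Cd86) lower and 7 not passing, and the same counts adjusted over the list alone. H2-Oa, a class II chaperone gene, rose 2.11-fold, from 388 ± 25.0 to 818 ± 39.7 FPKM, and the class I gene H2-K1 1.73-fold, from 1572 ± 87.5 to 2721 ± 72.4 FPKM. B2m, the gene of the class I light chain, rose 1.64-fold and the class II gene H2-Eb1 1.48-fold. Major histocompatibility genes have close paralogs, which could share fragments. The median log2 fold change of the list was 0.35 (camera adjusted p 3.7e-06, adjusted p = 0.27 with an estimated correlation). The median was 0.14 after quantile normalization, where 11 were called higher, and 0.22 with values rescaled to TPM, where 14 were higher and 2 lower. Macrophages and dendritic cells also express these genes, and macrophage markers rose in the same libraries, as given below.

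NF-kB pathway genes moved apart, with 7 of 24 tested higher and 7 lower, and 8 and 7 adjusted over the list alone. Traf1, a signalling adaptor gene, rose 2.28-fold, from 16.01 ± 0.157 to 38.0 ± 4.02 FPKM, while Tnfrsf13c, which encodes the receptor of the survival factor BAFF, fell 1.58-fold, from 398 ± 5.67 to 251 ± 8.71 FPKM. The inhibitor gene Nfkbia rose 1.35-fold and Nfkbiz 1.83-fold. Toll-like receptor pathway genes had 2 of 20 higher, Tlr7 (1.498-fold) and Ly86 (1.19-fold), and 2 lower, Tlr1 (1.51-fold) and Irf5 (1.42-fold), as when adjusted over the list alone. Tlr7 encodes an endosomal receptor for RNA. With the GC content and length trend removed 4 NF-kB genes were lower, and with values rescaled to TPM 1 Toll-like receptor gene was higher and 5 lower. Neither list was shifted, with camera adjusted p of 0.60 and 0.95.

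Trafficking and adhesion genes included 8 that rose and 7 that fell among 22 tested, and 8 and 9 adjusted over the list alone. Cxcr4, a chemokine receptor gene, rose 3.49-fold, from 18.998 ± 0.934 to 69.0 ± 7.98 FPKM, and Cxcr3 3.59-fold, from 0.517 ± 0.187 to 4.48 ± 0.962 FPKM. Itga4, an integrin gene, fell 2.10-fold and Lgals1, a galectin gene, 2.03-fold. Of 24 tested survival and apoptosis genes, 6 rose and 7 fell, and 6 and 8 adjusted over the list alone, but 4 were lower without WT replicate 2, without any 1 of the G9gl libraries or without a filter on low values. Fas, a death receptor gene, rose 2.14-fold, from 6.53 ± 0.953 to 15.1 ± 0.996 FPKM, and Bcl2a1d 1.76-fold. Neither list was shifted, with camera adjusted p of 0.80 and 0.96.

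Ribosomal protein genes rose almost as a set, with 60 of 65 tested higher and 0 lower, and 61 higher adjusted over the list alone. Those not passing were Rpl13a, Rpl26, Rpl30, Rps25 and Rps27. Rpl3 rose from 893 ± 20.6 to 1269.8 ± 48.7 FPKM and Rpsa from 772 ± 16.03 to 1089 ± 47.9 FPKM, 1.42-fold and 1.41-fold. The median log2 fold change was 0.33 (camera adjusted p 4.3e-20, adjusted p = 0.35 with an estimated correlation). It was 0.20 with values rescaled to TPM, where 45 were called higher, 0.21 with the GC content and length trend removed, where 49 were, and 0.13 after quantile normalization, where 24 were called higher and 1, Rps25, lower.

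Of 34 tested cell cycle genes, 15 rose, 2 (Cdkn1b and E2f2) fell and 17 did not pass, and 17 and 3 were called adjusted over the list alone. Top2a, a topoisomerase gene of dividing cells, rose from 1.66 ± 0.121 to 4.23 ± 0.992 FPKM and Birc5, which encodes survivin, from 1.26 ± 0.799 to 5.80 ± 1.98 FPKM. Cdk4, a cyclin-dependent kinase gene, rose 1.28-fold and Rrm2, a ribonucleotide reductase gene, 1.62-fold. The list was shifted up (median 0.27, camera adjusted p 9.5e-05, adjusted p = 0.35 with an estimated correlation). Without WT replicate 1 or WT replicate 2, 9 were higher, without WT replicate 1 or G9gl replicate 2, 1 was lower, and with values rescaled to TPM 10 were higher and 4 lower, with a median of 0.15. With a filter of at least 5 FPKM, 9 of 22 were higher.

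Oxidative phosphorylation genes had 19 of 61 called higher, 0 lower and 42 not passing, with 23 higher adjusted over the list alone, but 2 higher and 4 lower with values rescaled to TPM. Atp5g2, an ATP synthase subunit gene, rose 1.26-fold, from 347 ± 10.8 to 438 ± 4.51 FPKM, and Cox4i1, a cytochrome oxidase subunit gene, 1.23-fold. The camera adjusted p was 3.1e-05, with an adjusted p = 0.44 with an estimated correlation. After a trend on GC content and transcript length was removed, 6 members were higher and the camera adjusted p was 0.37. The number higher was 9 without WT replicate 2 or G9gl replicate 2, 12 without G9gl replicate 1 or with the replicate number as a block, 10 without a filter on low values and 8, with 1 lower, after quantile normalization. Of 20 tested glycolysis genes, 5 rose (Ldha, Pgam1, Gapdh, Aldoa and Tpi1), as adjusted over the list alone, with Ldha, the lactate dehydrogenase A gene, 1.35-fold higher, but with values rescaled to TPM 3 were higher and 3 lower. On the same list 1 gene was lower without WT replicate 1 or with library weights, and 2 with the GC content and length trend removed. Of 31 tested genes of the unfolded protein response and secretory pathway, 4 rose (Hspa5, Pdia4, Herpud1 and Manf) and 2 fell, again the same adjusted over the list alone. Hspa5, an endoplasmic reticulum chaperone gene, rose 1.31-fold and Eif2ak3, the gene of the stress sensor PERK, fell 1.69-fold, with Edem1 1.33-fold lower. On that list 2 were higher without WT replicate 1, without a filter on low values, after quantile normalization or with the trend removed, and 1 without WT replicate 2 or with values rescaled to TPM. Neither of these lists was shifted, with camera adjusted p of 0.13 and 0.22.

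Markers of marginal zone B cells, the blood-filtering B cells at the edge of the follicle, were lower in the sorted Fo B cells of G9gl. Of 20 tested, 10 fell, 3 rose (S1pr3, Plac8 and Pdia4) and 7 did not pass, and 12 and 3 were called adjusted over the list alone. Cd36, a scavenger receptor gene, fell 2.77-fold, from 14.8 ± 0.638 to 4.73 ± 0.631 FPKM, and Cr2 2.13-fold. The sort gate took cells with low CD21, the product of Cr2, and any part of the gate in these decreases was not tested. Dtx1 and Hes5, which Notch signals induce, fell 1.88-fold and 2.41-fold. The median log2 fold change was -0.37 (camera adjusted p 7.3e-04, adjusted p = 0.21 with an estimated correlation).

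Markers of follicular B cells were not shifted as a list (camera adjusted p 0.29, 0.045 after quantile normalization), with 3 of 16 higher, among them Cd22 and Cr1l, and 7 lower, and 5 and 9 adjusted over the list alone. Cxcr5, the gene of the follicle homing receptor, fell 1.41-fold, from 204 ± 12.5 to 144 ± 8.06 FPKM, and Ms4a1, which encodes CD20, 1.34-fold. Without WT replicate 2, WT replicate 3 or G9gl replicate 3, 4 were lower, with values rescaled to TPM 1 was higher and 11 lower, and with the GC content and length trend removed 5 and 4. Among 14 tested transitional B cell markers, 4 fell and 4 rose, also when adjusted over the list alone, but 2 rose without WT replicate 1 or 2, without G9gl replicate 2 or 3 or without a filter on low values. Cd24a, which encodes a surface protein high on immature B cells, fell 3.01-fold, from 326 ± 20.6 to 108 ± 12.6 FPKM, Vpreb3, a surrogate light chain-related gene, 2.43-fold, from 403 ± 15.8 to 166 ± 15.3 FPKM, and Sox4 and Cecr2 2.46-fold and 2.45-fold. Those that rose were Spn, Ms4a4c, Crisp3 and Stmn1, and the list was not shifted (camera adjusted p 0.58).

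Plasma cell markers had 8 of 16 higher and 2 (Irf4 and Fkbp11) lower, and 8 and 3 adjusted over the list alone, with 1 lower without WT replicate 2 or without a filter on low values. Jchain, which encodes the joining chain of secreted antibodies, rose from 0.579 ± 0.195 to 6.23 ± 0.776 FPKM and Fam46c from 0.804 ± 0.371 to 5.10 ± 1.26 FPKM, while Irf4, a transcription factor gene needed by plasma cells, fell 1.44-fold. Pou2af1, a B cell coactivator gene, rose 1.39-fold. The list was shifted up, except with a filter of at least 5 FPKM or with the GC content and length trend removed, where the camera adjusted p was 0.061 each time (median 0.26, camera adjusted p 0.0083, adjusted p = 0.27 with an estimated correlation). With values rescaled to TPM the median was 0.14, with 7 higher and 3 lower.

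Age-associated and atypical B cell markers split, with 6 of 19 higher and 7 lower, as adjusted over the list alone. Tbx21 rose 5.51-fold, Zeb2, a transcription factor gene, 2.33-fold, from 5.07 ± 0.578 to 13.2 ± 1.86 FPKM, and Cxcr3 3.59-fold, while S100a6 fell 5.59-fold. Germinal centre markers had 4 higher (Fas, S1pr2, Rgs13 and Cd38) and 4 lower (Bcl6, Gna13, Lmo2 and Myo1c) of 12, also adjusted over the list alone, with Rgs13, a G protein signalling regulator gene, 2.001-fold higher and Cd38 1.40-fold. Of the germinal centre markers 2 were lower without WT replicate 1 or 2 or G9gl replicate 2 or 3, and 7 of 19 were higher without a filter on low values. Memory markers had 3 higher (Cd38, Zeb2 and Ccr6) and 3 lower (Hhex, Tle3 and Skil) of 13, and 5 and 3 adjusted over the list alone. B1 cell markers had 3 higher (Apoe, Plscr1 and Spn) and 2 lower (Nid1 and Arl5c) of 13, and 4 and 2 adjusted over the list alone, with 1 lower without any 1 of the WT libraries, without G9gl replicate 3 or with no filter or a stricter filter on low values. The camera adjusted p of these 4 lists were 0.79, 0.60, 0.60 and 0.22, so none was shifted, although the B1 list reached 0.033 with values rescaled to TPM. The age-associated list had a median and mean of 0.011 and 0.012 and a camera direction of down, and its median changed sign between settings, from -0.099 with values rescaled to TPM to 0.062 without WT replicate 2.

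Among markers of other cell types, those of monocytes and macrophages rose from a list median of 0.895 FPKM in WT to 2.36 FPKM in G9gl, with 12 of 15 tested higher, 0 lower, and Adgre1, Cd68 and Ctsb not passing, and 13 higher adjusted over the list alone. C1qb and C1qc, complement genes of tissue macrophages, rose from 2.08 ± 0.793 to 8.11 ± 0.829 FPKM and from 1.75 ± 0.577 to 7.07 ± 0.662 FPKM, Vcam1 from 1.17 ± 0.149 to 3.21 ± 0.317 FPKM and the lysozyme gene Lyz2 from 6.57 ± 1.39 to 13.2 ± 1.19 FPKM. The list was shifted up (median 0.85, camera adjusted p 2.7e-08, adjusted p = 0.086 with an estimated correlation), with a median of 1.33 at a pseudocount of 0.1. Without a filter on low values 13 of 27 were higher, with a median of 0.57. Its member Ly6c2 also stands on the interferon and plasma cell lists.

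Of 8 tested dendritic cell markers, 4 rose (Zbtb46, Sirpa, Cd209a and Bst2) and 1, Naaa, fell, and 4 and 3 were called adjusted over the list alone, with Zbtb46 from 0.409 ± 0.233 to 1.95 ± 0.461 FPKM (list camera adjusted p 0.22). The call for Naaa was lost in 8 of the alternative settings, among them without any 1 of the WT libraries or without G9gl replicate 1 or 3, and with values rescaled to TPM 3 dendritic cell markers were lower. The call for Cd209a was lost without WT replicate 2 or 3, without G9gl replicate 3 and without a filter on low values, with adjusted p up to 0.086. Of 8 tested T cell markers, Lck, a Src-family kinase gene, rose 2.61-fold, from 37.4 ± 3.36 to 99.3 ± 10.4 FPKM, also adjusted over the list alone, and the others did not pass, with Cd8b1 at 0.785 ± 0.468 FPKM in WT and 1.33 ± 0.258 FPKM in G9gl and a list camera adjusted p of 0.49. Cd2, which B cells also express, passed as lower with values rescaled to TPM (log2 fold change -0.23, adjusted p 0.0064), after quantile normalization (adjusted p 0.020) and with the GC content and length trend removed (adjusted p 0.0034). All 4 tested NK cell markers were higher, also adjusted over the list alone, but the median over the list of 16 was 0.146 FPKM in WT and 0.132 FPKM in G9gl, and without a filter on low values 3 of 15 were higher with a median log2 fold change of 0.055. They were Prf1, the perforin gene, from 1.73 ± 0.535 to 6.44 ± 1.57 FPKM, Klrd1 from 0.30003 ± 0.138 to 1.49 ± 0.249 FPKM, Ccl5 from 1.81 ± 0.547 to 4.94 ± 1.57 FPKM and Nkg7 from 1.32 ± 0.509 to 2.32 ± 0.242 FPKM, whose call (adjusted p 0.049) was lost in 11 alternative settings.

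Among the lists too short for camera, the neutrophil gene S100a8 rose from 2.44 ± 1.44 to 13.3 ± 5.06 FPKM, the globin genes Hbb-b1 and Hbb-b2 rose 2.25-fold and 2.08-fold and Car2, the carbonic anhydrase 2 gene, fell 2.01-fold. The calls for both globin genes were lost without a filter on low values and with a robust eBayes fit, and that for Hbb-b1 without WT replicate 2 (adjusted p 0.076). S100a9 was at 2.15 ± 1.43 FPKM in WT and 5.21 ± 3.57 FPKM in G9gl (adjusted p 0.20), and Hba-a1 at 36.4 ± 9.24 FPKM in WT and 101 ± 92.1 FPKM in G9gl (adjusted p 0.20). S100a9 passed as higher without G9gl replicate 2 (adjusted p 0.024) and Hba-a1 without G9gl replicate 3 (adjusted p 0.018). Pecam1, the only tested member of the stromal and endothelial list, fell 1.40-fold, and the calls for these 3 lists were the same adjusted over the list alone. Xist, transcribed from the inactive X chromosome, was at 18.98 ± 2.74 FPKM in WT and 22.3 ± 1.54 FPKM in G9gl (adjusted p 0.16), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 6 libraries.

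**Figure D3:**
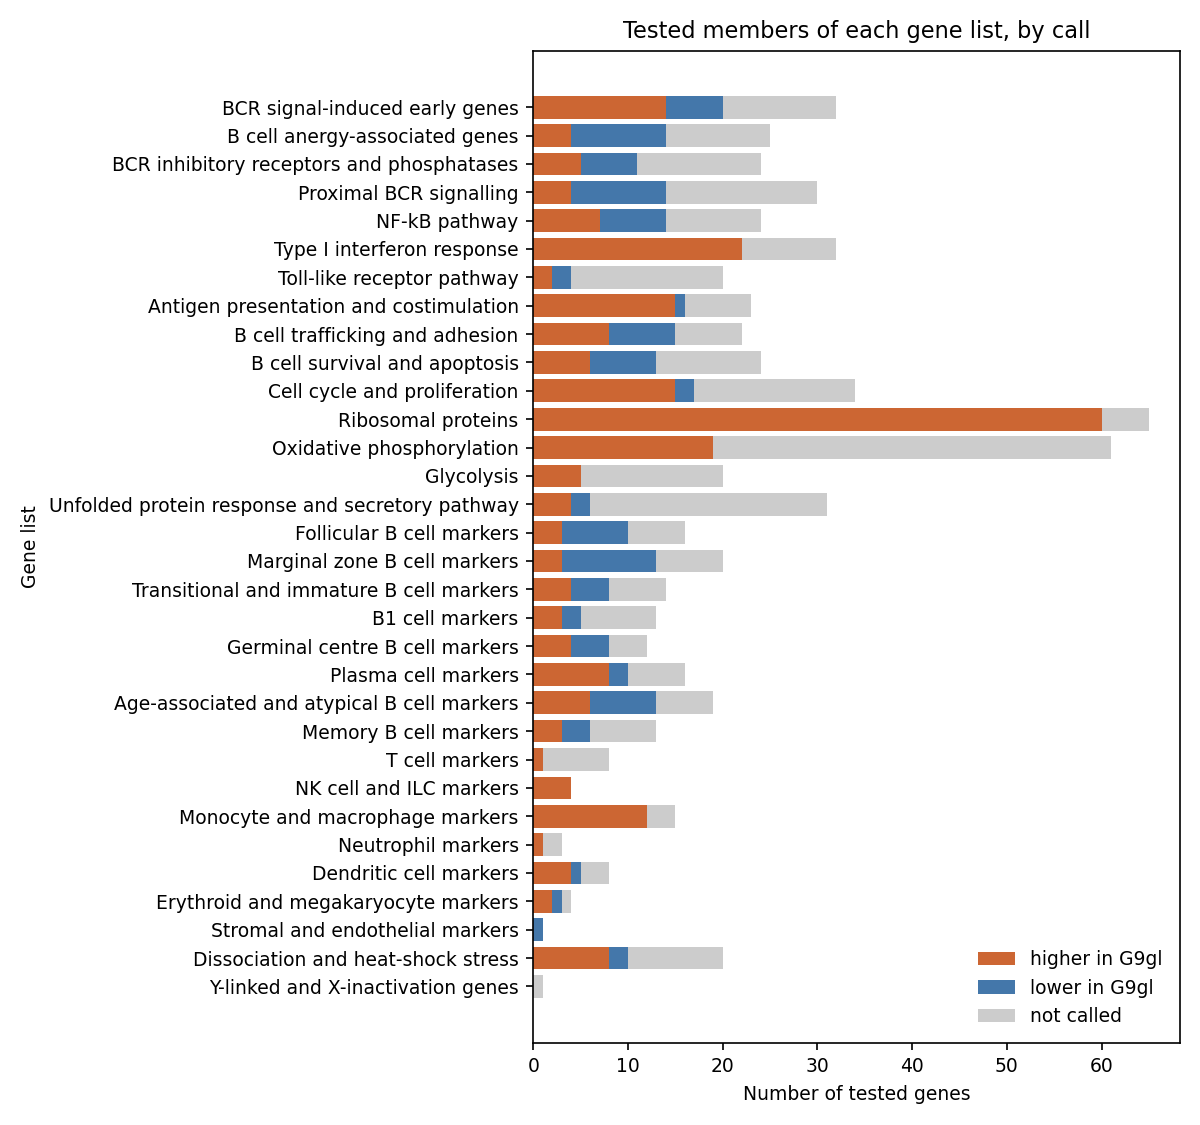
Number of tested genes per gene list on the horizontal axis, split into those called higher in G9gl (orange), lower in G9gl (blue) and not called (grey) at a limma adjusted p under 0.05. Ribosomal protein genes have 60 of 65 higher and interferon response genes 22 of 32, while the marginal zone list has 10 of 20 lower.

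Il9r and Rhbdf1 lie beside one another on chromosome 11, and their tested neighbours were looked at after these values were seen. Snrnp25, a spliceosome component gene between them, rose 3.21-fold, from 80.2 ± 4.48 to 259.8 ± 6.80 FPKM. Mpg, a DNA glycosylase gene, rose 1.99-fold and Nprl3, which encodes a regulator of mTORC1, 1.77-fold, so that 5 neighbouring genes from 32187541 to 32267707 (mm10) were higher. Mpg and Nprl3 overlap in the annotation. The next tested genes were Hba-a1 and Ubtd2, which did not pass, and Stk10, a kinase gene, which fell 1.49-fold. The 5 tested genes on the other side did not pass.

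**Figure D4:**
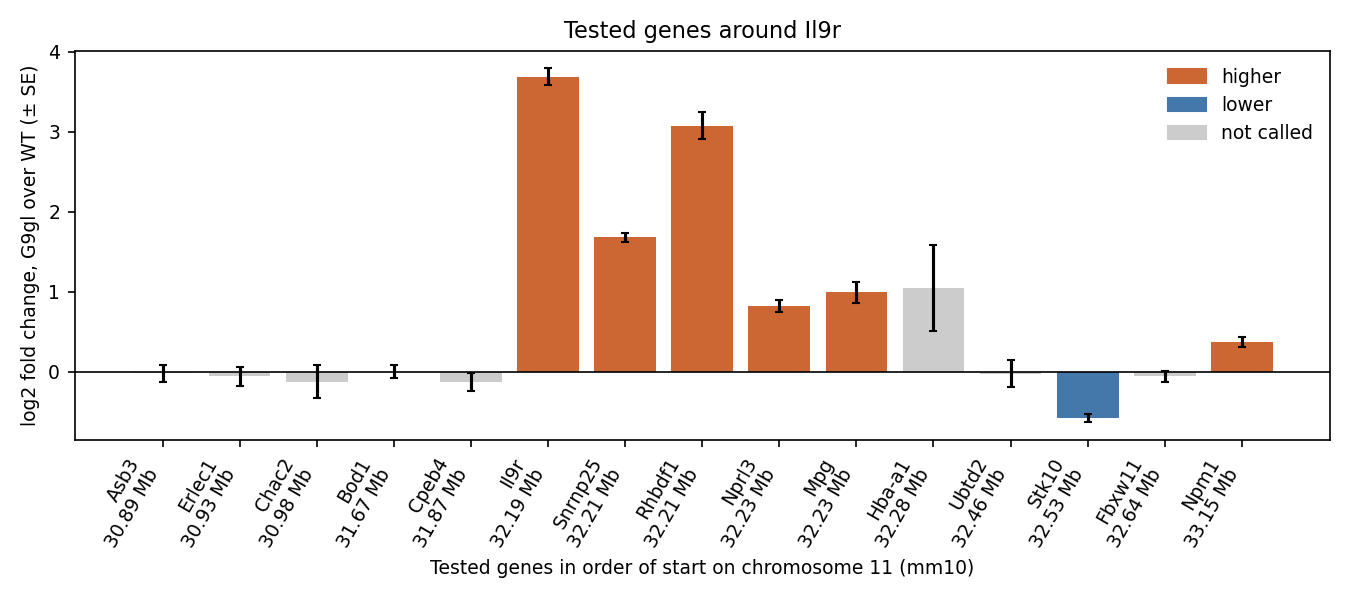
Log2 fold change of G9gl over WT, with its SE, for 15 tested genes in order of their start on chromosome 11 (mm10). Bars are orange for genes called higher, blue for lower and grey for not called. Il9r, Snrnp25, Rhbdf1, Nprl3 and Mpg are all higher.

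Across all 10122 tested genes the libraries separated by genotype. The first principal component held 59.7% of the variance and parted WT from G9gl, and the second held 13.5%, with G9gl replicate 1 and WT replicate 3 at its ends. Pearson correlations across genes, which are not independent replicates, were 0.988 to 0.992 within a genotype and 0.970 to 0.976 between genotypes. Of the tested genes, 40.8% had libraries that did not overlap between genotypes, against 10% by chance.

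The share of called genes that were higher depended on the scaling. It was 50.4% with the FPKM values and 22.7% with values rescaled to TPM, which moved the median log2 fold change of all tested genes to -0.13. Of the 27 lists tested, 11 were shifted with camera's preset correlation (9 up and 2 down), 0 with an estimated correlation, where the smallest adjusted p was 0.086, and 21 with fry, which does not compare a list with other genes.

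**Figure D5:**
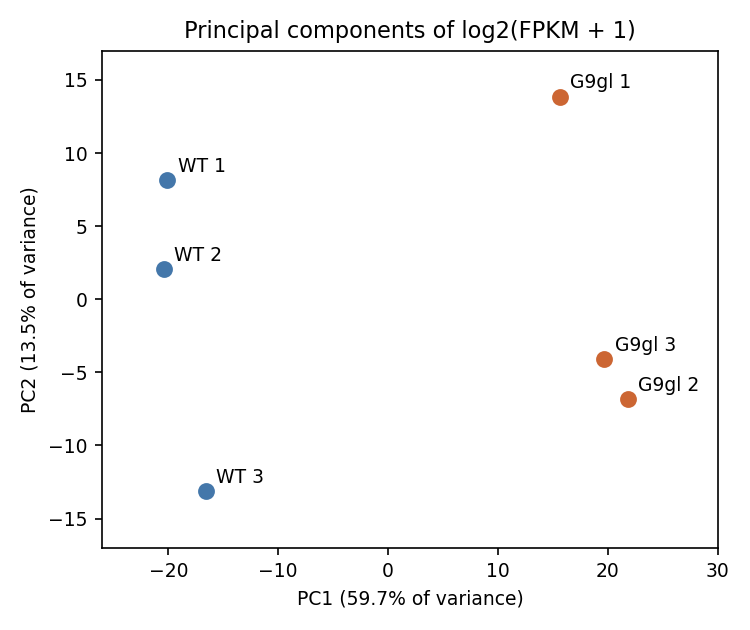
First and second principal components of log2(FPKM + 1) over the tested genes, with the share of variance on each axis. Each point is 1 library, WT in blue and G9gl in orange. The first component, with 59.7% of the variance, separates the genotypes.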

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

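The rescaling to TPM and the removal of a GC content and transcript length trend were chosen after the results were seen; the other alternatives were planned. With log2 fold changes of at least 1, 149 genes were higher and 108 lower, by construction fewer. Rescaled to TPM, 730 were higher and 2493 lower, since each G9gl library has the larger FPKM total over the genes analysed here, which leave out immunoglobulin genes. Leaving out each library in turn gave 827 to 1136 higher and 718 to 1172 lower genes, the lowest of both without WT replicate 2, with 1 library fewer. No gene called in the original fit was called in the opposite direction under any of the 17 refits. The lists shifted numbered 10 to 11 with a library left out, 0 with an estimated correlation and 21 with fry, which tests another question. For the macrophage, marginal zone and plasma cell lists the estimated correlations were -0.019, -0.045 and -0.039, below the preset 0.01. A higher correlation can therefore not explain the loss of these calls, and its cause was not tested. For the other lists shifted the estimate was above 0.01, up to 0.57 for ribosomal protein genes and 0.60 for interferon genes.

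Genes that reversed were not called originally, and the cause was not tested. After quantile normalization log2 fold changes were 0.022 for Egr3, -0.16 for Rps25, which was then called lower, and -0.16 for Rps27. With library weights they were -0.10 for Nr4a1 and 0.0016 for Egr3. Rescaled to TPM they were -0.0038 for Rps25 and -0.052 for Rps27, and with the GC and length trend removed -0.0098 and -0.033. Leaving out 1 library gave ranges of -0.43 to 0.52 for Nr4a1, -0.11 to 0.066 for Egr3, -0.18 to 0.60 for Rpl26, -0.12 to 0.29 for Rps27 and -0.18 to 0.096 for Ubtd2. Of 3297 values for 196 genes taken by the naming rule or chosen later, 3120 kept direction and side of the threshold, 148 became weaker (most often Nkg7 and Myc, in 11 and 9 settings, then Blnk, Gna13, Herpud1, Manf and Naaa, in 8 each, Jund in 7, Bcl10, Spn and Stmn1 in 6, Arl5c, Hhex, Hist1h2ac and Lmo2 in 5, and Cd209a, Cd22 and Pdia4 in 4), 11 stronger and 18 reversed. Of 457 values for 27 lists the numbers were 445, 10, 2 and 0.

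With the replicate number as a block, 1044 genes were higher and 988 lower, and 11 lists were shifted. The deviations of same-numbered libraries correlated at 0.099, -0.069 and 0.021, so the numbers were not taken to pair the libraries, and not every library correlated best with its own number. The planned tests of endogenous immunoglobulin variable genes and the rescaling without immunoglobulin genes were not run. At 9270000 to 10910000 fragments per library, genes near 1 FPKM rest on few fragments.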

Other observations

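The tests of Apoe and the macrophage list, of GC content and transcript length and of gene position were chosen after the changes they bear on were seen, and the count of other splits of the libraries was planned before. For GC content and transcript length the outcome that a trend would give was fixed before the corrected values were computed.

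Genes changed at least 2-fold included groups of neighbours beyond Il9r. On chromosome 11 (mm10), the chemokine genes Ccl3, Ccl4 and Ccl5, which attract leukocytes, rose 4.203-fold, 7.62-fold and 2.09-fold, and the nearby Wfdc17 rose 2.97-fold, from 64.0 ± 4.66 to 209 ± 109.5 FPKM (SD, n = 3 per group). On chromosome 13 the histone genes Hist1h4d, Hist1h1e and Hist1h2bc fell 2.13-fold, 2.203-fold and 2.36-fold. The call for Hist1h4d was lost without a filter on low values (adjusted p 0.057) and that for Wfdc17 with a robust eBayes fit (adjusted p 0.055). Histone genes have near copies that can share fragments. Near the Igh locus on chromosome 12, where Akt1, Serpina3f and Serpina3g also lie, Crip1, a LIM domain protein gene, fell from 1043 ± 55.3 to 478 ± 18.7 FPKM, and Rcor1, which encodes a corepressor, from 24.7 ± 2.96 to 8.53 ± 1.51 FPKM, while Adam6b, which lies within the locus, rose from 0.425 ± 0.265 to 2.44 ± 0.459 FPKM.

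The first pattern is the rise of Apoe and of macrophage markers. Were a larger share of macrophages in the sort the whole cause of the Apoe rise of 933.5 FPKM, their abundant transcripts should rise on that scale, but the sum of Lyz2, C1qa, C1qb, C1qc, Csf1r, Vcam1, Hmox1 and Cd5l rose by 28.5 FPKM, from 17.3 ± 3.20 to 45.8 ± 2.90 (SD, n = 3 per group). That argues against macrophages as the source of most of the Apoe rise. Of the 12 tested macrophage-list members under 10 FPKM in WT, 10 (83.3%) were called higher, but this counts the rise itself again, in genes that could enter the test through their G9gl values, and decides nothing. A small gain of macrophages or of their RNA, despite a sort on B220, CD21 and CD23, stays open for the rise of the list. A difference in Apoe expression in B cells between genotypes stays open as a hypothesis and was not tested.

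The second pattern is the rise of ribosomal protein genes together with the 2-fold decreases. A trend between libraries on GC content and transcript length was considered for both. The genes at least 2-fold lower had a median transcript length of 3446 bases, against 3270 for tested genes. Their median GC content was 53.0% against 49.4%, so such a trend could hardly have picked them out. After this trend was removed, the 101 genes at least 2-fold lower with a known length kept a median log2 fold change of -1.27, from -1.30, and 100 of them kept their call. The ribosomal protein genes kept 0.22 of 0.33 when the trend was fitted without them, which argues against the trend as the whole cause of either group, though part of the ribosomal rise went with it. Scaling stays open for much of the ribosomal rise, since the median was 0.20 with values rescaled to TPM and 0.13 after quantile normalization, where 24 of 65 were higher in place of 60, and a difference between genotypes stays open as well.

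The third pattern is the position of genes changed at least 2-fold. The highest number of them among 10 neighbouring tested genes was 5, reached in shuffled gene orders with a p of 0.01 (10000 permutations, one-sided). Shared regulation of neighbours stays a hypothesis and was not tested. Within 10 Mb of the Igh and Igk loci, where DNA carried over with the knock-in might lie, 7 of 110 genes (6.36%) changed at least 2-fold against 236 of 9623 (2.45%) elsewhere, an odds ratio of 2.70 (95% interval 1.05 to 5.86, two-sided Fisher's exact p 0.020). With the paralogs Serpina3f and Serpina3g counted as 1 gene it was 2.32 (0.823 to 5.29, p 0.054). By locus, 6 of 66 tested genes near Igh changed at least 2-fold and 1 of 44 near Igk, so the excess lay near Igh. Carried-over DNA, effects of the knock-in on its neighbours and a B cell response that includes these genes cannot be told apart with so few genes.

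Of the 10 splits of the 6 libraries into 3 and 3, 1, the split by genotype, called as many genes as the 2365 observed, and the highest of the other splits called 1. With 10 splits the share cannot fall under 0.1, so this count alone cannot reach the 0.05 level. Every other split mixed the genotypes, so their difference entered the spread within groups. Its low count therefore does not measure how many genes would be called by chance.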
